A study of Mus musculus with 12 samples.

How the data were processed

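RNA was measured in the 12 libraries described by the labels, 3 in each of 4 groups. Per the labels' protocols, marrow of mice about 8 weeks old was cultured for about 24 hours, RNA of the non-adherent cells was extracted with a Qiagen RNeasy Plus Micro kit, and libraries were made with a Clontech low-input poly(A) protocol. Reads were aligned with STAR and counted with featureCounts against mm10, per the submitters' processing notes; versions, annotation and strand setting are not given in the sources used here. The deposited table holds whole-number counts per gene symbol and library, not normalized by the authors. It lists 55291 symbols, of which 22077 had 0 counts in every library, and 96.4% of the symbols were found in the GENCODE M21 annotation of mm10, from which coordinates were taken. Without a strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of near-identical copies may have been divided or dropped.

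Totals of 16954355 to 20748995 counts set a floor of 3 counts for a gene with 0 counts, 0.0515 to 0.0538 CPM over the 3 libraries of a group. Folds against a group with 0 counts are given against that floor. Replicate pairs differed by more than sampling noise in every group (chi-square per degree of freedom 15.7 to 140), so none was treated as 1 library deposited again; this covers counting error only and does not show separate mice.

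Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr by group), which left 15674 genes. All 12 libraries entered 1 fit with 4 group means, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were genotype without SCFA, genotype under SCFA, SCFA in each genotype, the interaction, and genotype averaged over treatments. The comparisons, the alternatives, 37 gene lists and the rule for naming genes were chosen before the data were examined. Lists with at least 3 measured members were tested with camera (limma 3.58.1) on log2 CPM computed here with a prior count of 2, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A list is said to hold when both adjusted p are under 0.05.

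Named genes are, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and, between 2 groups, no overlap of their libraries, without unnamed gene models and antigen receptor segments. The rule also names 3 members with the smallest p of each list with a call, and always Stat3, Socs3, Cd4, Tnfrsf11a, Csf1r, Ffar2 and Xist. For brevity the text gives only the first 2 members, of lists that passed camera, in the 4 comparisons between 2 groups, a choice made after the values were seen. The values of 1 named gene, which is included in the counts, are not reported here. Ebf1 in untreated mice is given as a level for comparison with SCFA mice.

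The procedure was tested on simulated counts of 15674 genes, 200 of them changed. Without any change it called 0 genes in each comparison. With changed genes, 4 of 53 calls (7.55%) were false for the interaction, 5 of 80 (6.25%) for SCFA in homozygous mice and 3.12% to 4.35% in the others. For genotype without SCFA it recovered 31 of 67 genes changed 2-fold and 41 of 66 changed 4-fold, and for the interaction 11 of 67 and 38 of 66.

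Alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, only the libraries of the groups compared, the replicate number as a block, fry for lists, and each library left out in turn. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.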

Results

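RNA-seq counts were available for the non-adherent progenitor cells of mouse bone marrow, taken from mice about 8 weeks old and kept for about 24 hours in the culture medium alpha-MEM. The 12 libraries formed 4 groups of 3, and each is named by its group and replicate number, as in control untreated 2. Control mice and mice labelled homozygous for a STAT3C allele were each left untreated or given short-chain fatty acids (SCFAs) in the drinking water. The genotype label of homozygous untreated 1 names the Rosa26 locus, unlike those of the other 5 homozygous libraries; all 6 were taken as 1 genotype, by their titles. STAT3C is a constitutively active form of STAT3, a transcription factor downstream of interleukin 6 and related cytokines. The allele sits at the Rosa26 locus behind a stop cassette, which a Cre recombinase under the CD4 promoter removes, mainly in T cells. SCFAs are products of fibre fermentation by gut bacteria. The title of the study names bone loss in arthritis through osteoclasts, the bone-resorbing cells that arise from myeloid progenitors.

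Total counts ranged from 16954355 to 20748995 per library, and 20101 to 22272 genes had at least 1 count. A gene with 0 counts in a library may have had up to 0.145 to 0.177 CPM (3 counts per library), a limit that covers counting error only. All 12 libraries were from males by their counts: Xist, the transcript of the inactive X chromosome, had at most 3 counts, and the Y-linked Ddx3y had 1835 to 3772. The labels date every untreated library to day 1 and every SCFA library to day 30 of month 3, so that treatment and date cannot be told apart in any comparison of SCFA with no treatment. The labels do not say that the 3 libraries of a group came from separate mice, and p-values here measure only the spread between these libraries. On the first principal component (24.7% of the variance), homozygous SCFA libraries lay between 59.8 and 70.6, homozygous untreated libraries between 4.92 and 8.13 and control libraries between -39.3 and -34.5. Control untreated 2 stood apart on the second component (17.8%) at 87.4, against 4.63 and 41.5 for the other libraries of its group.

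Stat3 (chromosome 11, 100885098 to 100939540 on mm10, a protein-coding gene) had 357 ± 82.0 CPM in control untreated, 294 ± 27.3 in homozygous untreated, 239.7 ± 13.9 in control SCFA and 363 ± 40.3 in homozygous SCFA libraries (mean ± SD, n = 3). Its log2 fold change between genotypes was -0.28 ± 0.15 (SE, adjusted p = 0.221) without SCFA, which did not pass the test, and it rose by 0.60 ± 0.15 (SE, adjusted p = 0.0157) under SCFA. Counts per gene do not separate transcripts of the STAT3C allele from those of the endogenous gene, and the noncoding Rosa26 transcript had at most 16 counts per library, so these levels do not check the genotype labels. Socs3, a feedback inhibitor that STAT3 induces, had 143 ± 30.2, 90.1 ± 15.2, 70.7 ± 12.3 and 151 ± 28.5 CPM in the same order. The call of Stat3 without SCFA was gained in 1 of 12 fits without 1 library, with adjusted p at 0.0219 without control untreated 1 and from 0.0219 to 0.628 over all alternatives. The call of Stat3 under SCFA was lost in 3 of 12 fits without 1 library, with adjusted p at 0.0735 without homozygous SCFA 3 and from 4.2e-04 to 0.0735 over all alternatives.

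**Figure D1:**
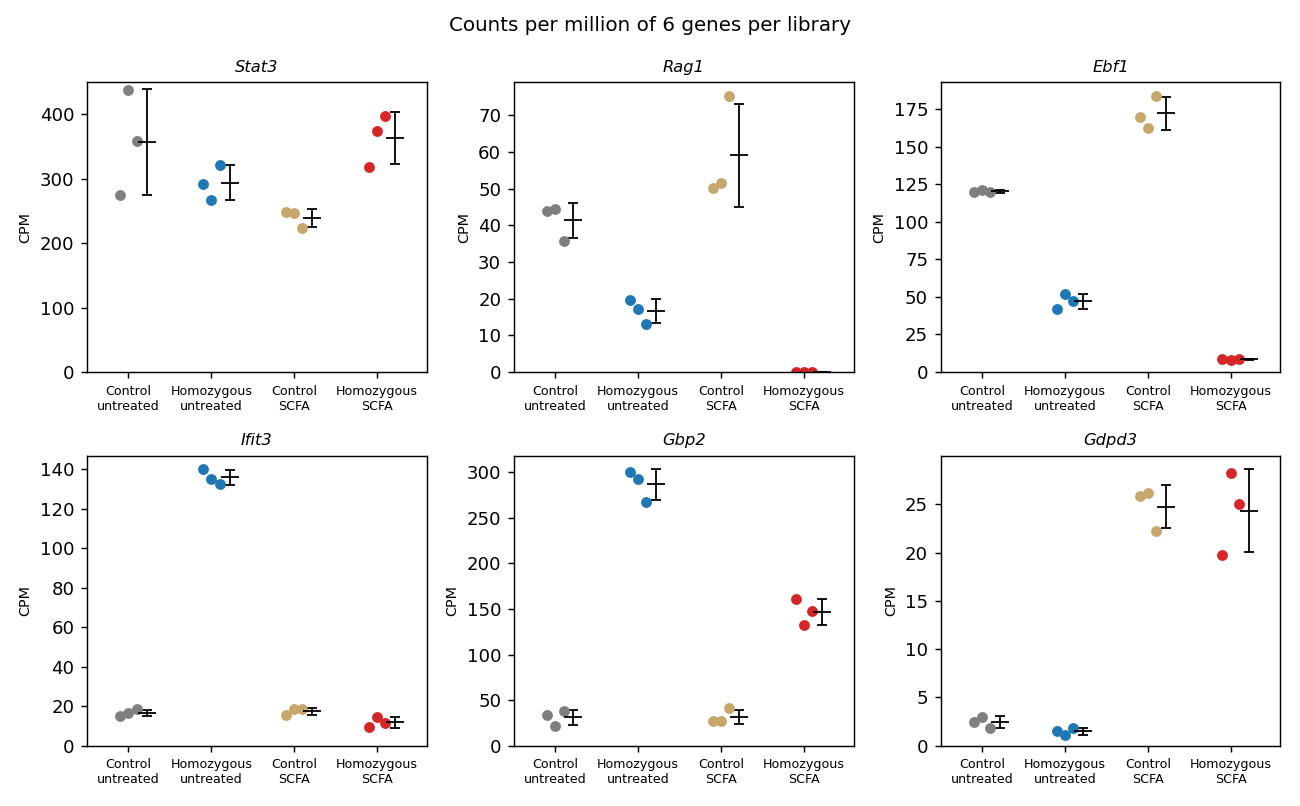
Counts scaled to library size (CPM, vertical axes, starting at 0) of 6 genes in each library, by group (horizontal axes); points are the 3 libraries of a group and the bar beside them is their mean with SD. Rag1 had 0 counts in the 3 homozygous SCFA libraries and 59.1 ± 14.0 CPM in control SCFA libraries, and Ifit3 stood at 136 ± 3.96 CPM in homozygous untreated libraries against 16.6 ± 1.70 in control untreated libraries.

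The first comparison asked how homozygous mice differed from control mice without SCFA. Interferon-induced genes were higher in homozygous mice, and B lineage genes were lower. The GTPase gene Iigp1 rose from 1.49 ± 0.957 to 68.5 ± 7.39 CPM (mean ± SD, n = 3; log2 fold change 5.49 ± 0.46 (SE, adjusted p = 4.7e-06)), and the guanylate-binding protein gene Gbp2 from 31.3 ± 8.38 to 286 ± 16.9 CPM (log2 fold change 3.20 ± 0.21 (SE, adjusted p = 6.9e-07)). Ifit3, an interferon-induced inhibitor of viral replication, rose by 3.03 ± 0.17 (SE, adjusted p = 1.7e-07) on the log2 scale. In the opposite direction, Ebf1, a transcription factor that specifies the B lineage, had 120.2 ± 1.01 CPM in control and 47.1 ± 5.13 CPM in homozygous mice. On mm10 Iigp1 lies on chromosome 18, 60376027 to 60392634, Gbp2 on chromosome 3, 142620602 to 142638008, Ifit3 on chromosome 19, 34583531 to 34588731 and Ebf1 on chromosome 11, 44617317 to 45008091, and all 4 are annotated as protein-coding.

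Of 15674 genes tested with edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 1048 rose and 1275 fell, 239 and 442 of them by at least 2-fold. Other large rises in log2 fold change were 3.85 (adjusted p = 0.010) for Eda2r, 3.51 (adjusted p = 6.3e-05) for Serpina3f, 3.15 (adjusted p = 8.3e-06) for Ifit3b, 3.15 (adjusted p = 3.9e-05) for Tgtp1 and 2.96 (adjusted p = 4.3e-04) for Ifi205. Eda2r is a receptor for ectodysplasin A2, Serpina3f a serine protease inhibitor, Tgtp1 an interferon-induced GTPase and Ifi205 an interferon-induced protein. The largest falls were -3.87 (adjusted p = 4.3e-04) for Tmem132e, -3.27 (adjusted p = 8.3e-06) for Dtx1, -3.05 (adjusted p = 4.4e-05) for Col5a3 and -2.34 (adjusted p = 0.00243) for Srpk3. Then came -2.26 (adjusted p = 1.9e-04) for Tmem108, -2.08 (adjusted p = 1.5e-06) for Fam129c, -2.07 (adjusted p = 3.2e-04) for Reln and -2.05 (adjusted p = 2.6e-05) for Blk. Dtx1 regulates Notch signalling, Col5a3 encodes a collagen chain, Reln encodes reelin, and Blk is a kinase of B cells. Ifit3 and Ifit3b, Tgtp1 and the Gbp genes have near-identical copies, so reads may have been divided between them.

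Of the type I interferon response genes, 24 rose and 0 fell of 28 (24 and 0 adjusted over the list alone), at a median of 1.25 and camera adjusted p = 6.4e-26 (adjusted p = 8.0e-05 with an estimated correlation). Oasl2, an interferon-induced gene, rose by 2.13 (adjusted p = 1.7e-07). In the interferon-gamma response 12 rose and 0 fell of 17 (13 and 0 adjusted over the list alone), at a median of 0.83 and camera adjusted p = 6.9e-11 (adjusted p = 0.00405 with an estimated correlation), and Igtp rose by 1.39 (adjusted p = 3.4e-06). Of the B lineage genes, 0 rose and 13 fell of 17 (0 and 15 adjusted over the list alone), at a median of -1.27 and camera adjusted p = 3.6e-11 (adjusted p = 0.00118 with an estimated correlation). Among them Cd79b, a chain of the B cell receptor complex, fell by 1.66 (adjusted p = 1.2e-06) and Ighm, the heavy chain of IgM, by 1.49 (adjusted p = 1.2e-06). The calls of these 3 lists held with an estimated correlation, and those of the 12 other lists that passed camera did not.

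Among immediate early genes, which respond within minutes to stimulation, 1 rose and 12 fell of 15 (1 and 13 adjusted over the list alone), at a median of -0.61 and camera adjusted p = 9.8e-07 (adjusted p = 0.120 with an estimated correlation). The log2 fold change was -1.03 (adjusted p = 5.4e-05) for Egr1 and -1.85 (adjusted p = 4.8e-04) for Egr2. Of the monocyte markers, 11 rose and 0 fell of 16 (12 and 1 adjusted over the list alone), at a median of 0.68 and camera adjusted p = 2.0e-07 (adjusted p = 0.0523 with an estimated correlation). Ly6c2 was at 1.11 (adjusted p = 4.6e-05) and Ms4a6c at 1.01 (adjusted p = 1.6e-04). Ly6c2 has a close paralog. Of the late neutrophil genes, 7 rose and 2 fell of 18 (10 and 3 adjusted over the list alone), at a median of 0.29 and camera adjusted p = 0.0354 (adjusted p = 0.196 with an estimated correlation). Mmp8 was at 0.62 (adjusted p = 0.00222) and S100a9 at 0.71 (adjusted p = 0.00646). Eosinophil, basophil and mast cell markers had 6 rises and 0 falls among 16 (6 and 1 adjusted over the list alone), at a median of 0.30 (0.11 without control untreated 2) and camera adjusted p = 0.0356 (adjusted p = 0.196 with an estimated correlation). Fcer1a was at 1.56 (adjusted p = 9.0e-04) and Mcpt8 at 0.75 (adjusted p = 4.9e-04). In the erythroid list 2 rose and 7 fell of 17 (3 and 8 adjusted over the list alone), at a median of -0.31 (-0.47 without homozygous untreated 3) and camera adjusted p = 0.0368 (adjusted p = 0.196 with an estimated correlation), and the alpha globin genes, which are near-identical copies, had log2 fold changes of -1.77 (adjusted p = 4.0e-05) for Hba-a1 and -1.74 (adjusted p = 3.6e-05) for Hba-a2.

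T cell markers had 0 rises and 3 falls among 21 (0 and 3 adjusted over the list alone), at a median of -0.37 and camera adjusted p = 0.00742 (adjusted p = 0.0563 with an estimated correlation). Lck was at -0.94 (adjusted p = 0.00948) and Lef1 at -1.13 (adjusted p = 0.00107). Plasmacytoid dendritic cell markers had 0 rises and 3 falls among 9 (1 and 4 adjusted over the list alone), at a median of -0.42 and camera adjusted p = 0.0159 (adjusted p = 0.278 with an estimated correlation). Ly6d was at -1.81 (adjusted p = 1.6e-05) and Spib at -1.89 (adjusted p = 2.5e-05), genes that B cells also express. Of the histone deacetylases, 0 rose and 4 fell of 11 (1 and 7 adjusted over the list alone), at a median of -0.45 and camera adjusted p = 0.00339 (adjusted p = 0.196 with an estimated correlation). Hdac9 was at -1.45 (adjusted p = 1.9e-04) and Hdac7 at -1.28 (adjusted p = 0.00496). G2 and M phase genes had 7 rises and 1 falls among 21 (9 and 2 adjusted over the list alone), at a median of 0.28 and camera adjusted p = 0.00339 (adjusted p = 0.0507 with an estimated correlation). Ccnb1 was at 0.68 (adjusted p = 0.00793) and Cdk1 at 0.57 (adjusted p = 0.00781). Heat shock genes had 2 rises and 0 falls among 10 (5 and 0 adjusted over the list alone), at a median of 0.49 and camera adjusted p = 0.00458 (adjusted p = 0.0545 with an estimated correlation). Hsp90aa1 was at 0.80 (adjusted p = 0.0268) and Hspd1 at 0.53 (adjusted p = 0.0169). Oxidative phosphorylation genes had 8 rises and 0 falls among 21 (8 and 0 adjusted over the list alone), at a median of 0.13 (0.20 without homozygous untreated 2) and camera adjusted p = 0.0409 (adjusted p = 0.217 with an estimated correlation). Cycs was at 0.78 (adjusted p = 0.00888) and Ndufb5 at 0.64 (adjusted p = 0.0137). For the mitochondrially encoded genes, which have nuclear copies, 0 rose and 0 fell of 12 (0 and 0 adjusted over the list alone), at a median of 0.47 (0.97 without control untreated 1 and 0.26 without control untreated 2) and camera adjusted p = 0.00610 (adjusted p = 0.468 with an estimated correlation); mt-Co3 was at 1.00 (adjusted p = 0.0771) and mt-Co1 at 0.49 (adjusted p = 0.126), neither past the test.

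For genes of osteoclast differentiation and function, 2 rose and 5 fell of 19 (3 and 5 adjusted over the list alone), at a median of -0.23 and camera adjusted p = 0.374, and the list did not pass. Tnfrsf11a, the gene of the RANK receptor through which osteoclasts form, rose by 1.00 ± 0.19 (SE, adjusted p = 0.00496), whereas Csf1r, the receptor of the growth factor M-CSF, was at -0.25 (adjusted p = 0.314), Cd4 at -0.41 (adjusted p = 0.592) and the SCFA receptor gene Ffar2 at 0.20 (adjusted p = 0.563), none of these 3 past the test. Socs3 fell by 0.67 (adjusted p = 0.0355). The 3 libraries of one genotype did not overlap those of the other for 5068 genes (32.3%), against 10% by chance. The count of called genes was 4454 without control untreated 1, 881 without control untreated 2, 1170 without control untreated 3, 935 without homozygous untreated 1 and 823 without homozygous untreated 2, and it was 3922 with limma-voom and 827 in a fit of the 6 libraries compared. Hspd1, Hsp90aa1 and Ndufb5 lost the call in 4, 4 and 4 of 12 fits, as without control untreated 2 (adjusted p = 0.0766, 0.0993 and 0.0771). Lck lost the call in 1 of 12 fits, without homozygous untreated 1 (adjusted p = 0.050). Socs3 lost the call in 5 of 12 fits, as without homozygous untreated 2 (adjusted p = 0.164). mt-Co3, mt-Co1 and Csf1r gained the call in 1, 1 and 1 of 12 fits, without control untreated 1 (adjusted p = 0.00441, 0.00142 and 0.0210). Plasmacytoid dendritic cell markers lost the call in 1 of 12 fits, without control untreated 1 (adjusted p = 0.0759). Erythroid genes and mitochondrially encoded genes lost the call in 3 and 1 of 12 fits, as without control untreated 3 (adjusted p = 0.0589 and 0.0540). Late neutrophil genes, oxidative phosphorylation and eosinophil, basophil and mast cell markers lost the call in 3, 3 and 3 of 12 fits, as without homozygous untreated 1 (adjusted p = 0.0751, 0.0823 and 0.0751). Plasma cell genes and NK and cytotoxic cell markers gained the call in 2 and 2 of 12 fits, as without control untreated 2 (adjusted p = 0.0320 and 0.0320). Conventional dendritic cell and MHC class II genes gained the call in 1 of 12 fits, without homozygous untreated 3 (adjusted p = 0.0442). Over all alternatives except fry for genotype without SCFA, adjusted p ranged from 3.0e-05 to 0.778 for these genes and from 1.0e-05 to 0.468 for these lists.

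**Figure D2:**
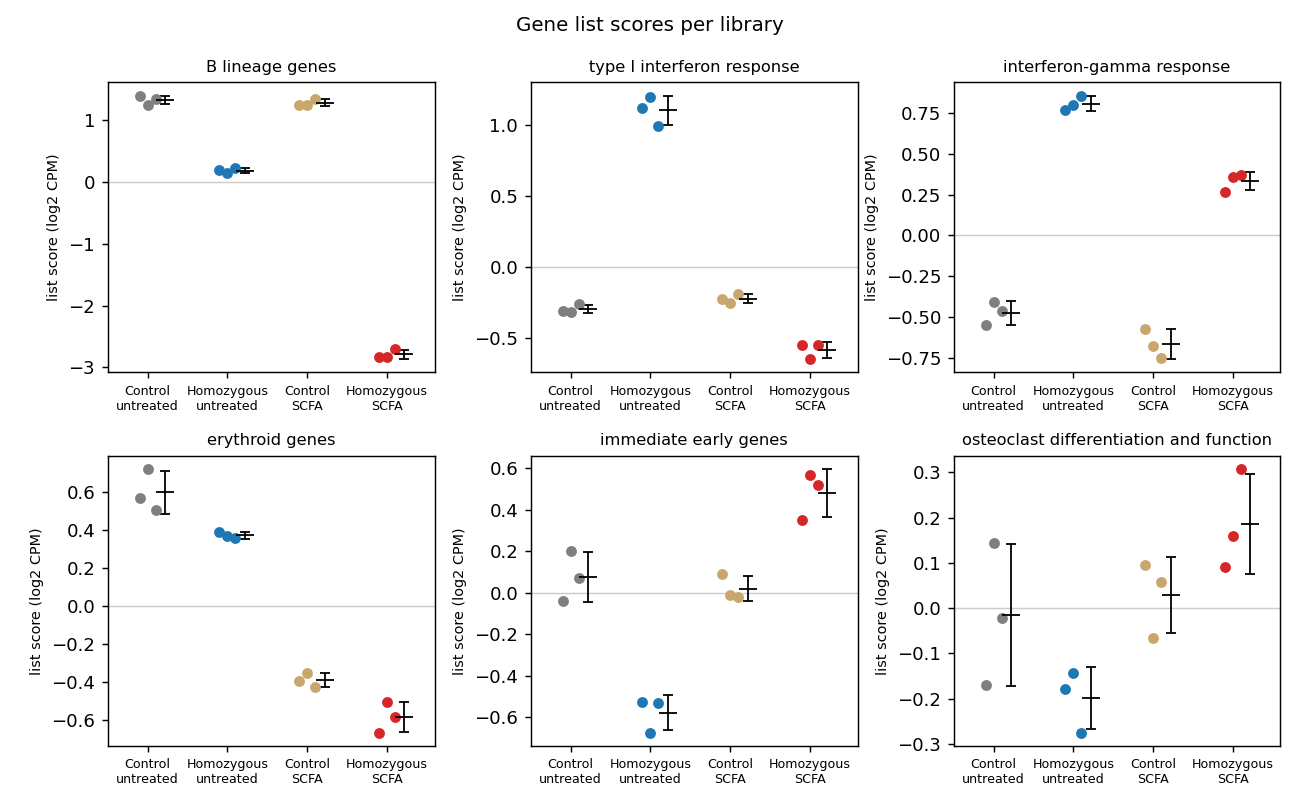
Mean log2 CPM of 6 gene lists per library, each gene centred on its mean over the 12 libraries (vertical axes, log2 scale), by group (horizontal axes); points are the 3 libraries of a group and bars their mean with SD. B lineage scores lay between 1.25 and 1.38 in control libraries and between -2.84 and -2.71 in homozygous SCFA libraries, and type I interferon scores lay between 0.989 and 1.20 in homozygous untreated libraries.

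The same genotype difference was then measured under SCFA. B lineage genes were lower in homozygous SCFA mice. Rag1 and Rag2, the recombinase genes that assemble antigen receptors, had 59.1 ± 14.0 and 40.9 ± 1.78 CPM in control SCFA libraries (mean ± SD, n = 3) and 0 counts in all 3 homozygous SCFA libraries. Against the limit of 3 counts over the group, this was at least 1078-fold lower for Rag1 (adjusted p = 3.2e-09) and at least 760.4-fold lower for Rag2 (adjusted p = 4.2e-08). Igll1, the surrogate light chain of the pre-B cell receptor, had 3 counts against 1274, a ratio between 0.000507 and 0.00721 (95% exact interval for counting error; adjusted p = 4.5e-09). Ebf1 fell from 172 ± 10.9 to 8.37 ± 0.305 CPM, a log2 fold change of -4.36 ± 0.13 (SE, adjusted p = 5.5e-11). Rag1 lies on chromosome 2, 101638282 to 101649501, Rag2 on chromosome 2, 101624718 to 101632529 and Igll1 on chromosome 16, 16860671 to 16863985 of mm10.

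With edgeR, 1394 genes rose and 1328 fell, 256 and 743 of them by at least 2-fold. Another 5 genes named by size had 0 counts in the homozygous SCFA group and were lower there by at least 449.6-fold for Col5a3 (adjusted p = 8.6e-08), 448-fold for Gfra1, a receptor of the growth factor GDNF (adjusted p = 2.0e-08), 310.2-fold for Tnfrsf19 (adjusted p = 1.3e-07), 304-fold for the R-spondin receptor Lgr5 (adjusted p = 3.0e-07) and 251-fold for Sertad4 (adjusted p = 4.0e-07). Car1, a carbonic anhydrase of erythroid cells, rose from 0.474 ± 0.779 to 50.6 ± 7.72 CPM (log2 fold change 6.67 ± 0.81 (SE, adjusted p = 6.6e-05; fitted 10.59 without control SCFA 2, on 1 count)). The next largest rises were 4.29 (adjusted p = 0.00587; fitted 8.79 without control SCFA 2, on 1 count) for Eda2r, 3.74 (adjusted p = 0.00689; 6.47 without control SCFA 1) for Colec12, 3.35 (adjusted p = 1.4e-06) for Csta2 and 3.02 (adjusted p = 2.6e-05) for Cstdc5. Then came 2.89 (adjusted p = 9.6e-05) for Stfa2, 2.68 (adjusted p = 5.0e-04) for Iigp1 and 2.38 (adjusted p = 3.0e-07) for Asprv1. Csta2, Cstdc5 and Stfa2 belong to the stefins, inhibitors of cysteine proteases, whose close copies may share reads. Colec12 is a scavenger receptor and Asprv1 a protease.

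Of the B lineage genes, 0 rose and 16 fell of 17 (0 and 16 adjusted over the list alone), at a median of -3.37 and camera adjusted p = 8.1e-28 (adjusted p = 7.2e-05 with an estimated correlation); the median was the same with Rag1 and Rag2 at their bound. Cd79b fell by 2.99 (adjusted p = 1.2e-09). Interferon-gamma response genes were again higher: 13 rose and 0 fell of 17 (14 and 0 adjusted over the list alone), at a median of 0.94 and camera adjusted p = 2.1e-08 (adjusted p = 0.0136 with an estimated correlation). Gbp2 was at 2.21 (adjusted p = 3.1e-06) and Gbp3 at 1.31 (adjusted p = 7.3e-05). These 2 lists held with an estimated correlation, and the other 12 that passed camera did not. In the type I interferon response 2 rose and 10 fell of 28 (2 and 11 adjusted over the list alone), at a median of -0.39 and camera adjusted p = 0.00755 (adjusted p = 0.0869 with an estimated correlation). Rsad2 was at -2.26 (adjusted p = 1.6e-07) and Isg15 at -1.22 (adjusted p = 1.6e-04). For plasmacytoid dendritic cell markers 0 rose and 7 fell of 9 (0 and 7 adjusted over the list alone), at a median of -2.61 and camera adjusted p = 2.5e-08 (adjusted p = 0.0869 with an estimated correlation). Spib was at -3.97 (adjusted p = 9.4e-09) and Ly6d at -3.01 (adjusted p = 3.8e-08). Plasma cell genes had 0 rises and 4 falls among 9 (1 and 4 adjusted over the list alone), at a median of -1.76 and camera adjusted p = 0.0224 (adjusted p = 0.174 with an estimated correlation), and the members that fell most clearly, -3.24 (adjusted p = 3.6e-08) for Irf4 and -4.46 (adjusted p = 6.9e-05) for Eaf2, are also expressed by other B cells.

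Among myeloid lists, 7 rose and 0 fell of 10 (8 and 0 adjusted over the list alone), at a median of 0.59 and camera adjusted p = 0.00125 (adjusted p = 0.285 with an estimated correlation) for the primary granule genes of early neutrophils, with 0.97 (adjusted p = 0.00204) for Prtn3 and 0.65 (adjusted p = 0.00616) for Fcnb. Of the late neutrophil genes, 8 rose and 1 fell of 18 (8 and 1 adjusted over the list alone), at a median of 0.16 and camera adjusted p = 0.0409 (adjusted p = 0.269 with an estimated correlation). Camp was at 0.90 (adjusted p = 0.00127) and Il1r2 at -0.62 (adjusted p = 0.00106). Of the monocyte markers, 5 rose and 0 fell of 16 (6 and 0 adjusted over the list alone), at a median of 0.30 and camera adjusted p = 0.00790 (adjusted p = 0.269 with an estimated correlation). Fn1 was at 0.84 (adjusted p = 0.00473) and Cd14 at 0.74 (adjusted p = 0.0122). The megakaryocyte and platelet list had 7 rises and 0 falls among 12 (7 and 0 adjusted over the list alone), at a median of 0.72 and camera adjusted p = 8.5e-05 (adjusted p = 0.179 with an estimated correlation). Vwf was at 1.12 (adjusted p = 0.00139) and Gp9 at 1.40 (adjusted p = 0.00183). STAT3 target genes had 10 rises and 0 falls among 18 (13 and 0 adjusted over the list alone), at a median of 0.65 and camera adjusted p = 2.3e-05 (adjusted p = 0.179 with an estimated correlation). Saa3 was at 0.82 (adjusted p = 5.0e-04), Lrg1 at 1.24 (adjusted p = 5.1e-04) and Socs3 at 1.09 (adjusted p = 0.00181). For immediate early genes, 8 rose and 0 fell of 15 (9 and 1 adjusted over the list alone), at a median of 0.54 and camera adjusted p = 3.7e-05 (adjusted p = 0.219 with an estimated correlation). Fos was at 0.68 (adjusted p = 7.3e-04) and Ier3 at 0.78 (adjusted p = 7.7e-04).

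Glycolysis genes had 10 rises and 0 falls among 15 (12 and 0 adjusted over the list alone), at a median of 0.81 and camera adjusted p = 2.7e-06 (adjusted p = 0.292 with an estimated correlation). Aldoa was at 0.94 (adjusted p = 0.00174) and Gapdh at 0.94 (adjusted p = 0.00155). Ribosomal protein genes had 11 rises and 1 falls among 28 (13 and 3 adjusted over the list alone), at a median of 0.36 and camera adjusted p = 0.00692 (adjusted p = 0.479 with an estimated correlation). Rpl18 was at 0.79 (adjusted p = 0.00267) and Rplp0 at 0.64 (adjusted p = 0.00560). Mitochondrially encoded genes had 0 rises and 1 falls among 12 (0 and 1 adjusted over the list alone), at a median of -0.55 (-0.34 without control SCFA 3) and camera adjusted p = 0.0333 (adjusted p = 0.523 with an estimated correlation). mt-Cytb was at -0.74 (adjusted p = 0.00994), while mt-Co3 at -1.04 (adjusted p = 0.0644) did not pass. The osteoclast list did not pass (6 rose and 1 fell of 19 (8 and 2 adjusted over the list alone), camera adjusted p = 0.0602). Csf1r rose by 0.96 ± 0.16 (SE, adjusted p = 0.00125), Tnfrsf11a was at 0.18 (adjusted p = 0.566), not past the test, Ffar2 rose by 0.69 (adjusted p = 0.0450) and Cd4 was lower at -2.00 (adjusted p = 0.0171). In 6196 genes (39.5%) the genotypes did not overlap, against 10% by chance. Fewer or more genes by over 1.5 times were called in fits without 1 library: 1723 without control SCFA 2, 1453 without control SCFA 3, 1512 without homozygous SCFA 2 and 1559 without homozygous SCFA 3. With limma-voom the count was 4762. Ffar2 and mt-Cytb lost the call in 8 and 1 of 12 fits, as without control SCFA 3 (adjusted p = 0.181 and 0.0695). Cd4 and Cd14 lost the call in 3 and 2 of 12 fits, as without homozygous SCFA 2 (adjusted p = 0.0837 and 0.0600). mt-Co3 gained the call in 2 of 12 fits, as without control untreated 1 (adjusted p = 0.0192). Late neutrophil genes lost the call in 2 of 12 fits, as without control SCFA 1 (adjusted p = 0.0846). Mitochondrially encoded genes lost the call in 3 of 12 fits, as without homozygous SCFA 3 (adjusted p = 0.0824). Histone deacetylases and erythroid genes gained the call in 3 and 1 of 12 fits, as without homozygous SCFA 2 (adjusted p = 0.0305 and 0.0347). Over all alternatives except fry for genotype under SCFA, adjusted p ranged from 2.4e-05 to 0.208 for these genes and from 0.00409 to 0.523 for these lists.

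SCFA and the label date differed together in the comparison of SCFA with untreated control mice. Here erythroid genes were lower in SCFA mice, and Gdpd3, a lysophospholipase D, was higher. Of the erythroid genes, 0 rose and 9 fell of 17 (0 and 12 adjusted over the list alone), at a median of -1.18 and camera adjusted p = 5.1e-07 (adjusted p = 0.0531 with an estimated correlation). Gdpd3 (chromosome 7, 126766334 to 126775649 on mm10) rose from 2.44 ± 0.600 to 24.8 ± 2.23 CPM (mean ± SD, n = 3; log2 fold change 3.34 ± 0.24 (SE, adjusted p = 1.7e-05)). Slc4a1, the band 3 anion exchanger of red cells, fell by 1.91 on the log2 scale (adjusted p = 2.0e-04), and Trim10, which acts in terminal erythroid differentiation, by 1.99 (adjusted p = 4.9e-05).

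By edgeR 1393 genes rose and 2039 fell, 232 and 426 of them by at least 2-fold. After Gdpd3 the largest rises were 1.97 (adjusted p = 3.4e-04) for Gucy1b1, 1.93 (adjusted p = 0.00111) for Hpgds, 1.90 (adjusted p = 0.0277) for Lrrn3 and 1.86 (adjusted p = 0.0165) for Slc15a2, then 1.72 (adjusted p = 0.0182; 1.03 without control SCFA 1) for Zfp808, 1.61 (adjusted p = 0.0111) for Dus4l and 1.54 (adjusted p = 0.00485) for Zscan26. Gucy1b1 is a subunit of soluble guanylate cyclase, Hpgds a prostaglandin D synthase, Slc15a2 a peptide transporter and Dus4l a tRNA-modifying enzyme. Beside Slc4a1 and Trim10, the largest falls were -2.11 (adjusted p = 4.6e-04) for Rhd, -2.11 (adjusted p = 9.8e-05) for Tmcc2 and -2.07 (adjusted p = 1.0e-04) for Trim58, then -2.00 (adjusted p = 0.00388) for Trib3, -1.82 (adjusted p = 0.00250) for Ypel4 and -1.78 (adjusted p = 0.00511) for Ccdc92b. Rhd encodes the Rhesus blood group antigen, Trim58 acts in late erythroid maturation, and Trib3 is a pseudokinase of the amino acid stress response.

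None of the 6 lists that passed camera held with an estimated correlation. Beside the erythroid list, primary granule genes of early neutrophils had 0 rises and 7 falls among 10 (0 and 8 adjusted over the list alone), at a median of -0.62 and camera adjusted p = 0.00162 (adjusted p = 0.595 with an estimated correlation). Mpo was at -0.91 (adjusted p = 0.00688) and Prtn3 at -0.87 (adjusted p = 0.00701). In glycolysis 0 rose and 10 fell of 15 (0 and 11 adjusted over the list alone), at a median of -0.65 and camera adjusted p = 8.4e-04 (adjusted p = 0.595 with an estimated correlation). Gpi1 was at -0.86 (adjusted p = 0.00662) and Eno1 at -0.77 (adjusted p = 0.00678). T cell markers had 0 rises and 3 falls among 21 (0 and 3 adjusted over the list alone), at a median of -0.57 and camera adjusted p = 0.00942 (adjusted p = 0.160 with an estimated correlation). Cd6 was at -2.02 (adjusted p = 0.0122) and Lck at -0.95 (adjusted p = 0.00819). For ribosomal protein genes 3 rose and 12 fell of 28 (5 and 13 adjusted over the list alone), at a median of -0.28 and camera adjusted p = 0.0229 (adjusted p = 0.616 with an estimated correlation). Rpl18 was at -0.84 (adjusted p = 0.00485) and Rplp0 at -0.77 (adjusted p = 0.00485). The mitochondrially encoded genes had 7 rises and 0 falls among 12 (10 and 0 adjusted over the list alone), at a median of 0.79 (1.33 without control untreated 1) and camera adjusted p = 8.4e-04 (adjusted p = 0.595 with an estimated correlation). mt-Co3 was at 1.32 (adjusted p = 0.0222) and mt-Cytb at 0.80 (adjusted p = 0.00884). B lineage genes (3 rose and 3 fell of 17 (5 and 6 adjusted over the list alone), median -0.18, camera adjusted p = 0.959) and type I interferon genes (5 rose and 7 fell of 28 (8 and 7 adjusted over the list alone), median 0.16, camera adjusted p = 0.782) did not pass as lists.

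Tnfrsf11a rose by 1.15 ± 0.20 (SE, adjusted p = 0.00431), while Csf1r fell by 0.48 (adjusted p = 0.0469), Socs3 by 1.02 (adjusted p = 0.00613) and Stat3 by 0.58 (adjusted p = 0.0192). As a list, osteoclast genes did not pass (3 rose and 5 fell of 19 (5 and 6 adjusted over the list alone), with a median of -0.13 and a mean of 0.05 that differ in sign, camera adjusted p = 0.991), nor did the list of SCFA receptors, transport and metabolism (1 rose and 1 fell of 11 (2 and 1 adjusted over the list alone), camera adjusted p = 0.513). Ffar2 was at -0.54 (adjusted p = 0.0955) and Cd4 at -0.19 (adjusted p = 0.808), neither past the test. The groups did not overlap for 6033 genes (38.5%), against 10% by chance. The count of called genes depended on single libraries: 5269 without control untreated 1, 1363 without control untreated 2, 2019 without control untreated 3, 1889 without control SCFA 2 and 690 without control SCFA 3. A fit of the 6 libraries compared called 1844. Zfp808 lost the call in 3 of 12 fits, as without control SCFA 1 (adjusted p = 0.104). Slc15a2, Cd6, Stat3, Csf1r, Lck and mt-Cytb lost the call in 3, 2, 3, 10, 1 and 1 of 12 fits, as without control SCFA 3 (adjusted p = 0.0789, 0.0650, 0.0894, 0.171, 0.0501 and 0.0608). Dus4l and mt-Co3 lost the call in 2 and 5 of 12 fits, as without control untreated 2 (adjusted p = 0.0531 and 0.108). Lrrn3 lost the call in 3 of 12 fits, as without control untreated 3 (adjusted p = 0.0966). Ribosomal protein genes lost the call in 2 of 12 fits, as without control untreated 1 (adjusted p = 0.101). Over all alternatives except fry for control mice, adjusted p ranged from 1.3e-10 to 0.171 for these genes and from 0.0113 to 0.616 for this list.

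In homozygous mice, SCFA and date again differed together. Type I interferon genes and B lineage genes were lower in SCFA than in untreated homozygous mice, erythroid genes were lower, and immediate early, megakaryocyte and macrophage genes were higher. Ifit3 fell from 136 ± 3.96 to 11.8 ± 2.64 CPM (mean ± SD, n = 3; log2 fold change -3.52 ± 0.17 (SE, adjusted p = 1.2e-08)), close to the 17.4 ± 1.76 CPM of control SCFA libraries. Egr1, an immediate early transcription factor (chromosome 18, 34859823 to 34864984 on mm10), rose from 42.3 ± 2.20 to 231 ± 5.87 CPM (log2 fold change 2.45 ± 0.12 (SE, adjusted p = 1.0e-08)). C1qa, a chain of complement C1q made by macrophages, rose by 2.03 (adjusted p = 2.4e-05), and Ebf1 fell by 2.49 (adjusted p = 1.5e-08).

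By edgeR 621 genes rose and 880 fell, 188 and 453 of them by at least 2-fold. Rises were largest for Gdpd3, at 4.01 (adjusted p = 1.2e-07), and then 2.87 (adjusted p = 0.00737) for Skint3, 2.74 (adjusted p = 0.0128) for Car1 and 2.64 (adjusted p = 1.2e-05) for Egr2. Then came 2.13 (adjusted p = 0.00360) for Plxna4 and 2.12 (adjusted p = 0.00202) for C4b, a semaphorin receptor and a complement component. With 0 counts in the homozygous SCFA libraries, Rag2 was at least 385-fold lower (adjusted p = 2.7e-07) and Rag1 at least 307-fold lower (adjusted p = 6.5e-08). Igll1 had 3 counts against 1100 (ratio 0.000583 to 0.00829, 95% exact interval for counting error; adjusted p = 1.5e-08). Other large falls were -4.74 (adjusted p = 1.0e-08) for Akap12, -4.62 (adjusted p = 8.2e-10) for Cecr2, -4.08 (adjusted p = 1.0e-08) for Fam129c and -3.67 (adjusted p = 8.9e-08) for Vpreb3. Vpreb3 is a chaperone of the pre-B cell receptor and Akap12 a scaffold of protein kinase A.

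In this comparison 19 lists passed camera, and 10 of them held with an estimated correlation. Of the type I interferon genes, 0 rose and 27 fell of 28 (0 and 27 adjusted over the list alone), at a median of -1.64 and camera adjusted p = 7.4e-35 (adjusted p = 2.5e-05 with an estimated correlation). Rsad2 was at -2.82 (adjusted p = 4.8e-08). Of the B lineage genes, 0 rose and 16 fell of 17 (0 and 16 adjusted over the list alone), at a median of -2.09 and camera adjusted p = 9.6e-28 (adjusted p = 3.8e-05 with an estimated correlation); the median was the same with Rag1 and Rag2 at their bound. Immediate early genes had 13 rises and 0 falls among 15 (14 and 0 adjusted over the list alone), at a median of 0.81 and camera adjusted p = 1.7e-14 (adjusted p = 0.0175 with an estimated correlation). Fos was at 1.85 (adjusted p = 7.4e-08). Megakaryocyte and platelet genes had 9 rises and 0 falls among 12 (11 and 0 adjusted over the list alone), at a median of 1.12 and camera adjusted p = 7.4e-10 (adjusted p = 0.0182 with an estimated correlation). Pf4 was at 1.49 (adjusted p = 3.0e-04) and Tubb1 at 1.25 (adjusted p = 1.8e-04). Plasmacytoid dendritic cell markers had 0 rises and 6 falls among 9 (0 and 7 adjusted over the list alone), at a median of -1.70 and camera adjusted p = 1.7e-09 (adjusted p = 0.0214 with an estimated correlation). Spib was at -2.50 (adjusted p = 1.3e-06) and Siglech at -2.00 (adjusted p = 7.3e-06). Erythroid genes had 3 rises and 12 falls among 17 (3 and 12 adjusted over the list alone), at a median of -1.62 and camera adjusted p = 2.1e-08 (adjusted p = 0.00844 with an estimated correlation). Alas2 was at -2.12 (adjusted p = 4.7e-07). Car1 went the other way.

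Macrophage markers had 6 rises and 1 falls among 16 (6 and 1 adjusted over the list alone), at a median of 0.69 and camera adjusted p = 2.0e-05 (adjusted p = 0.00844 with an estimated correlation). C1qc was at 1.82 (adjusted p = 1.0e-06) and Apoe at 1.80 (adjusted p = 1.3e-05). In the NF-kB driven inflammatory list 7 rose and 0 fell of 27 (10 and 1 adjusted over the list alone), at a median of 0.37 and camera adjusted p = 0.00110 (adjusted p = 0.0180 with an estimated correlation). Ccl3 was at 1.75 (adjusted p = 6.7e-06) and Ccl4 at 1.44 (adjusted p = 6.2e-05). G2 and M phase genes had 0 rises and 8 falls among 21 (0 and 12 adjusted over the list alone), at a median of -0.36 and camera adjusted p = 2.0e-05 (adjusted p = 0.00844 with an estimated correlation). Kif11 was at -0.64 (adjusted p = 0.00912) and Cdk1 at -0.53 (adjusted p = 0.0123). Heat shock genes had 0 rises and 6 falls among 10 (0 and 7 adjusted over the list alone), at a median of -0.55 and camera adjusted p = 1.8e-04 (adjusted p = 0.0169 with an estimated correlation). Hspa1a was at -2.53 (adjusted p = 0.00343) and Hspd1 at -0.59 (adjusted p = 0.0110).

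The 9 other lists did not hold. Genes of osteoclast differentiation and function had 7 rises and 1 falls among 19 (7 and 1 adjusted over the list alone), at a median of 0.33 and camera adjusted p = 0.00205 (adjusted p = 0.159 with an estimated correlation). Itgb3 was at 1.06 (adjusted p = 1.1e-04) and Car2 at -1.09 (adjusted p = 1.4e-05). Itgb3 is also a platelet integrin and Car2 an erythroid enzyme. Conventional dendritic cell and MHC class II genes had 5 rises and 0 falls among 13 (6 and 1 adjusted over the list alone), at a median of 0.60 (0.24 without homozygous untreated 2) and camera adjusted p = 0.00748 (adjusted p = 0.186 with an estimated correlation). H2-Ab1 was at 1.31 (adjusted p = 6.1e-05) and H2-Aa at 0.89 (adjusted p = 4.5e-05). In the interferon-gamma response 0 rose and 5 fell of 17 (1 and 7 adjusted over the list alone), at a median of -0.43 (-0.22 without homozygous untreated 3) and camera adjusted p = 0.00188 (adjusted p = 0.0576 with an estimated correlation). Irgm1 was at -1.54 (adjusted p = 3.4e-06) and Igtp at -0.58 (adjusted p = 0.00397). For S phase genes 0 rose and 5 fell of 18 (0 and 7 adjusted over the list alone), at a median of -0.26 and camera adjusted p = 0.00207 (adjusted p = 0.133 with an estimated correlation). Rrm2 was at -0.53 (adjusted p = 0.00793) and Mcm6 at -0.53 (adjusted p = 0.00852). STAT3 target genes had 5 rises and 0 falls among 18 (6 and 0 adjusted over the list alone), at a median of 0.21 (0.13 without homozygous SCFA 2) and camera adjusted p = 0.00891 (adjusted p = 0.277 with an estimated correlation). Saa3 was at 1.01 (adjusted p = 8.9e-05), Junb at 1.10 (adjusted p = 6.5e-04) and Socs3 at 0.74 (adjusted p = 0.0277).

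Plasma cell genes had 1 rises and 3 falls among 9 (1 and 5 adjusted over the list alone), at a median of -0.59 and camera adjusted p = 0.0302 (adjusted p = 0.101 with an estimated correlation). Irf4 was at -1.82 (adjusted p = 1.8e-05) and Eaf2 at -3.26 (adjusted p = 0.00142). In glycolysis 2 rose and 0 fell of 15 (3 and 0 adjusted over the list alone), at a median of 0.31 (0.16 without homozygous untreated 2) and camera adjusted p = 0.0141 (adjusted p = 0.552 with an estimated correlation). Aldoa was at 0.62 (adjusted p = 0.0325) and Slc16a3 at 0.71 (adjusted p = 0.0274). Unfolded protein and amino acid stress genes had 1 rises and 5 falls among 14 (1 and 6 adjusted over the list alone), at a median of -0.23 and camera adjusted p = 0.0291 (adjusted p = 0.194 with an estimated correlation). Hspa5 was at -0.66 (adjusted p = 0.00492) and Trib3 at -1.21 (adjusted p = 0.0225). Stromal and endothelial markers had 0 rises and 2 falls among 10 (0 and 2 adjusted over the list alone), at a median of -0.89 and camera adjusted p = 0.0303 (adjusted p = 0.101 with an estimated correlation). Emcn was at -3.09 (adjusted p = 0.0301; fitted -5.10 without homozygous SCFA 1, on 1 count) and Alpl at -2.81 (adjusted p = 0.0386; fitted -5.47 without homozygous SCFA 2, on 1 count). Csf1r rose by 0.73 (adjusted p = 0.0123) and Cd4 was lower at -1.78 (adjusted p = 0.0456; -2.78 without homozygous SCFA 3), whereas Stat3 at 0.31 (adjusted p = 0.240), Tnfrsf11a at 0.33 (adjusted p = 0.309) and Ffar2 at -0.05 (adjusted p = 0.928) did not pass. In 4725 genes (30.1%) the groups did not overlap, against 10% by chance. The count of called genes was 920 without homozygous untreated 1, 837 without homozygous untreated 2, 758 without homozygous SCFA 2 and 772 without homozygous SCFA 3, and it was 2310 with DESeq2 and 2988 with limma-voom. Cd4, Emcn, Hspd1 and Kif11 lost the call in 7, 4, 2 and 1 of 12 fits, as without homozygous SCFA 2 (adjusted p = 0.172, 0.121, 0.0580 and 0.0527). Alpl, Trib3 and Cdk1 lost the call in 9, 4 and 1 of 12 fits, as without homozygous SCFA 3 (adjusted p = 0.106, 0.106 and 0.0690). Car1 lost the call in 2 of 12 fits, as without homozygous untreated 1 (adjusted p = 0.0576). Slc16a3, Aldoa, Socs3 and Csf1r lost the call in 4, 4, 4 and 4 of 12 fits, as without homozygous untreated 2 (adjusted p = 0.126, 0.151, 0.130 and 0.0614). Plasma cell genes lost the call in 1 of 12 fits, without homozygous SCFA 3 (adjusted p = 0.0512). Stromal and endothelial markers and glycolysis lost the call in 1 and 2 of 12 fits, as without homozygous untreated 2 (adjusted p = 0.0662 and 0.0829). Unfolded protein and amino acid stress response lost the call in 3 of 12 fits, as without homozygous untreated 3 (adjusted p = 0.121). Over all alternatives except fry for homozygous mice, adjusted p ranged from 1.7e-26 to 0.222 for these genes and from 0.00278 to 0.552 for these lists.

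Whether the genotype difference itself depended on SCFA was tested as the interaction, in which a date effect common to both genotypes drops out; a positive value means that homozygous mice stood higher against control mice under SCFA than without it. Type I interferon genes stood lower against control mice under SCFA than without it, and the fall of B lineage genes was deeper under SCFA. For the type I interferon list, 0 rose and 25 fell of 28 (0 and 25 adjusted over the list alone), at a median of -1.69 and camera adjusted p = 1.9e-19 (adjusted p = 2.4e-04 with an estimated correlation). For the B lineage list, 0 rose and 15 fell of 17 (0 and 15 adjusted over the list alone), at a median of -2.41 and camera adjusted p = 5.1e-15 (adjusted p = 4.0e-04 with an estimated correlation). Both held with an estimated correlation; the other 8 lists that passed camera did not. The interferon-gamma list did not pass (3 rose and 6 fell of 17 (3 and 6 adjusted over the list alone), camera adjusted p = 0.618); its median of 0.16 and its mean of -0.28 differed in sign.

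By edgeR 2125 genes had a positive and 1813 a negative interaction, more than the 1585 genes called for genotype and the 1045 called for treatment when each was averaged over the other factor. The largest positive values were 3.68 (adjusted p = 0.0262; 6.38 without control SCFA 1) for Colec12, 3.43 (adjusted p = 0.0391; fitted 7.35 without control SCFA 2, on 1 count) for Car1, 2.54 (adjusted p = 0.00196) for Krt83 and 2.52 (adjusted p = 3.2e-05) for Apoe, followed by 2.34 (adjusted p = 0.00396) for Dip2a, 2.23 (adjusted p = 0.00131) for Egr2, 2.20 (adjusted p = 7.1e-04) for Myl9 and 2.18 (adjusted p = 0.00181) for Tab1. Apoe is the apolipoprotein made by macrophages, Krt83 a keratin, Myl9 a myosin light chain and Tab1 an adaptor of the kinase TAK1. Genes with 0 counts in the homozygous SCFA group had log2 interactions of at most -8.86 for Rag2, -8.76 for Rag1, -7.78 for Gfra1, -6.75 for Tnfrsf19, -6.75 for Lgr5, -6.07 for Sertad4 and -5.76 for Col5a3 (adjusted p from 5.4e-07 to 1.1e-04). Igll1 also had a negative interaction (adjusted p = 8.8e-07) that rests on 3 counts in the homozygous SCFA group.

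Immediate early genes had 13 rises and 0 falls among 15 (14 and 0 adjusted over the list alone), at a median of 1.04 and camera adjusted p = 7.3e-09 (adjusted p = 0.117 with an estimated correlation). For plasmacytoid dendritic cell markers 0 rose and 5 fell of 9 (0 and 6 adjusted over the list alone), at a median of -1.44 and camera adjusted p = 1.4e-04 (adjusted p = 0.211 with an estimated correlation). Glycolysis genes had 10 rises and 0 falls among 15 (11 and 1 adjusted over the list alone), at a median of 1.08 and camera adjusted p = 2.6e-04 (adjusted p = 0.470 with an estimated correlation). Mitochondrially encoded genes had 0 rises and 7 falls among 12 (0 and 7 adjusted over the list alone), at a median of -1.01 and camera adjusted p = 0.00342 (adjusted p = 0.493 with an estimated correlation). Among STAT3 target genes 9 rose and 1 fell of 18 (10 and 3 adjusted over the list alone), at a median of 0.92 and camera adjusted p = 0.00746 (adjusted p = 0.439 with an estimated correlation). In the megakaryocyte and platelet list 5 rose and 0 fell of 12 (5 and 0 adjusted over the list alone), at a median of 0.64 and camera adjusted p = 0.00985 (adjusted p = 0.439 with an estimated correlation). G2 and M phase genes had 1 rises and 12 falls among 21 (3 and 12 adjusted over the list alone), at a median of -0.68 and camera adjusted p = 0.0122 (adjusted p = 0.117 with an estimated correlation). Heat shock genes had 0 rises and 4 falls among 10 (0 and 4 adjusted over the list alone), at a median of -0.75 and camera adjusted p = 0.0213 (adjusted p = 0.151 with an estimated correlation). In these counts rose and fell refer to positive and negative interactions.

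Socs3 had an interaction of 1.76 ± 0.28 (SE, adjusted p = 0.00119), Stat3 of 0.88 ± 0.22 (SE, adjusted p = 0.0111), Csf1r of 1.21 ± 0.23 (SE, adjusted p = 0.00324) and Tnfrsf11a of -0.82 ± 0.27 (SE, adjusted p = 0.0390). Ffar2 at 0.49 (adjusted p = 0.263) and Cd4 at -1.59 (adjusted p = 0.113) did not pass. The osteoclast list did not pass (8 rose and 2 fell of 19 (9 and 2 adjusted over the list alone), camera adjusted p = 0.0678). Across genes, which are not independent replicates, the genotype log2 fold changes without and under SCFA had a Pearson correlation of 0.161 and a Spearman correlation of -0.105. The interaction count was 2540 without control SCFA 3 and 2599 without homozygous SCFA 2. The Pearson correlation was 0.0903 without control untreated 1, and the Spearman correlation was -0.0299 without control untreated 2, -0.0583 without homozygous untreated 2, -0.0615 without control SCFA 3 and -0.0629 without homozygous SCFA 2. Car1 lost the call in 10 of 12 fits, as without control untreated 1 (adjusted p = 0.170). Colec12 lost the call in 6 of 12 fits, as without control untreated 3 (adjusted p = 0.0701). Tnfrsf11a lost the call in 9 of 12 fits, as without homozygous SCFA 3 (adjusted p = 0.0921). Cd4 gained the call in 1 of 12 fits, without homozygous SCFA 3 (adjusted p = 0.0156). Osteoclast differentiation and function, monocyte markers and Y-linked genes gained the call in 1, 1 and 1 of 12 fits, without control untreated 1 (adjusted p = 0.0409, 0.0409 and 0.0398). Ribosomal protein genes gained the call in 3 of 12 fits, as without homozygous untreated 1 (adjusted p = 0.0135). Conventional dendritic cell and MHC class II genes gained the call in 5 of 12 fits, as without homozygous untreated 3 (adjusted p = 0.0327). Over all alternatives except fry for the interaction, adjusted p ranged from 2.9e-12 to 0.568 for these genes and from 0.0135 to 0.714 for these lists.

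**Figure D3:**
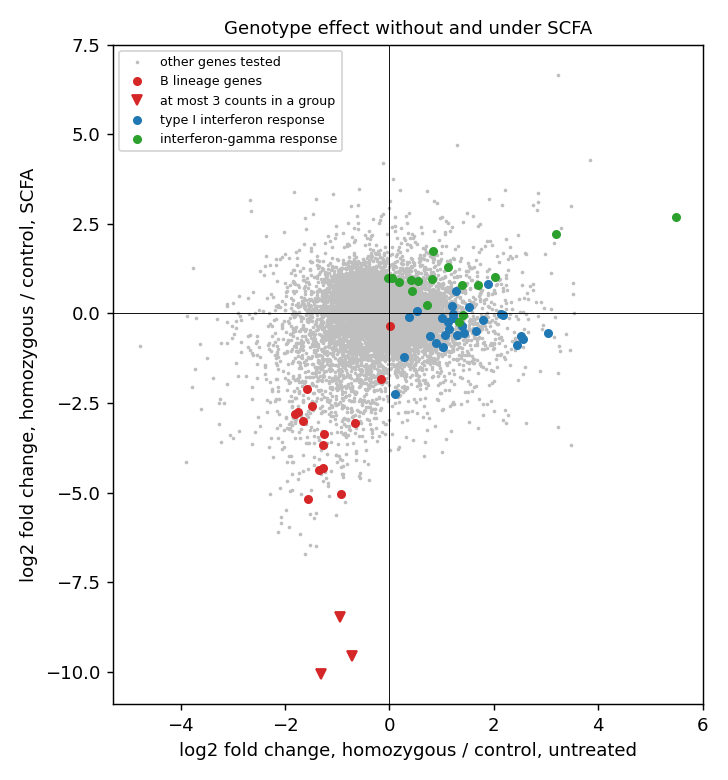
Log2 fold change of homozygous against control mice without SCFA (horizontal axis) and under SCFA (vertical axis); each point is 1 gene, with the B lineage, type I interferon and interferon-gamma lists in colour. Triangles are the 3 list members among 410 genes with at most 3 counts in a group, placed with that group at 3 counts, and the other genes of this kind are left out; B lineage genes lie lower under SCFA and type I interferon genes lie to the right.

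Averaged over both treatments, homozygous mice had higher interferon-gamma response genes and lower B lineage genes. In the interferon-gamma list 17 rose and 0 fell of 17 (17 and 0 adjusted over the list alone), at a median of 0.72 and camera adjusted p = 3.4e-18 (adjusted p = 6.2e-04 with an estimated correlation), with 4.09 ± 0.31 (SE, adjusted p = 3.0e-07) for Iigp1 and 2.70 ± 0.15 (SE, adjusted p = 9.9e-09) for Gbp2. The stefin genes Csta2, Cstdc5, Stfa2 and Stfa1 rose by 3.10 (adjusted p = 6.1e-08), 2.89 (adjusted p = 8.6e-07), 2.86 (adjusted p = 2.7e-06) and 1.98 (adjusted p = 3.0e-05). Of the B lineage genes, 0 rose and 16 fell of 17 (0 and 16 adjusted over the list alone), at a median of -2.33 and camera adjusted p = 2.4e-32 (adjusted p = 4.0e-05 with an estimated correlation); the median was the same with Rag1 and Rag2 at their bound. Type I interferon genes had 18 rises and 2 falls among 28 (21 and 2 adjusted over the list alone), at a median of 0.54 and camera adjusted p = 4.6e-13 (adjusted p = 6.0e-04 with an estimated correlation) and monocyte markers 10 rose and 0 fell of 16 (13 and 0 adjusted over the list alone), at a median of 0.49 and camera adjusted p = 8.3e-10 (adjusted p = 0.0292 with an estimated correlation). These 4 lists held with an estimated correlation, and 15 others that passed camera did not.

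By edgeR 562 genes rose and 1023 fell. Car1 rose by 4.95 (adjusted p = 2.0e-05) and Eda2r by 4.07 (adjusted p = 4.7e-04; fitted 6.32 without control SCFA 2, on 1 count). Bounds of the average log2 fold change, with the homozygous SCFA group at 3 counts, were -5.69 for Rag1, -5.93 for Col5a3, -5.14 for Rag2, -4.92 for Gfra1, -4.90 for Tnfrsf19, -4.87 for Lgr5 and -4.94 for Sertad4 (adjusted p from 3.4e-09 to 2.5e-07). Igll1 was also called (adjusted p = 6.9e-09). Tnfrsf11a rose by 0.59 (adjusted p = 0.0107) and Cd4 was lower at -1.21 (adjusted p = 0.0441), while Stat3 at 0.16 (adjusted p = 0.440), Socs3 at 0.21 (adjusted p = 0.408), Csf1r at 0.36 (adjusted p = 0.0642) and Ffar2 at 0.45 (adjusted p = 0.0926) did not pass.

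Median log2 fold changes of the lists that camera placed higher without holding were 0.30 for primary granule genes of early neutrophils, 0.22 for late neutrophil genes, 0.22 for STAT3 target genes, 0.24 for glycolysis, 0.30 for megakaryocyte and platelet genes and 0.16 for oxidative phosphorylation. Those of the lists it placed lower were -1.64 for plasmacytoid dendritic cell markers, -0.30 for histone deacetylases, -0.58 for erythroid genes and -1.64 for plasma cell genes. Camera also placed eosinophil, basophil and mast cell markers, NK and cytotoxic cell markers and ribosomal protein genes higher and stromal and endothelial markers lower. Their adjusted p lay between 1.0e-08 and 0.0343, and with an estimated correlation the adjusted p lay between 0.0546 and 0.589. The osteoclast list had a median of 0.17 and a mean of -0.01, which differ in sign (camera adjusted p = 0.420). The hypoxia list passed (adjusted p = 0.0222; adjusted p = 0.160 with an estimated correlation) with a median of 0.25 and a mean of -0.03, which differ in sign. The count of called genes was 2483 with limma-voom. Cd4 lost the call in 8 of 12 fits, as without homozygous SCFA 2 (adjusted p = 0.108). Ffar2 gained the call in 1 of 12 fits, without control SCFA 1 (adjusted p = 0.0444). Csf1r gained the call in 2 of 12 fits, as without control untreated 2 (adjusted p = 0.00950). Eosinophil, basophil and mast cell markers and stromal and endothelial markers lost the call in 2 and 3 of 12 fits, as without control untreated 2 (adjusted p = 0.0877 and 0.0834). Ribosomal protein genes lost the call in 2 of 12 fits, as without homozygous SCFA 2 (adjusted p = 0.0908). Hypoxia response and NK and cytotoxic cell markers lost the call in 2 and 2 of 12 fits, as without homozygous untreated 3 (adjusted p = 0.0536 and 0.0633). Over all alternatives for the average, adjusted p ranged from 3.0e-04 to 0.193 for these genes and from 9.2e-04 to 0.589 for these lists.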

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

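The tests of B cell stage, a shared date effect, an offset shared by a group and a shift of all genes, and comparing interaction with averaged counts, were chosen only after the result was seen. Values are log2 interactions (edgeR) or their medians over lists (camera), each past the test for a difference between the treatments in the effect of genotype. Of 136 genes named in the 4 comparisons between 2 groups, 98 had it, 37 positive and 61 negative, as had 10 lists.

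B cell, plasma cell and lymphoid genes had -5.10 for Akap12, -1.73 for Blk, 2.21 for Cd6, -1.33 for Cd79b, -3.90 for Eaf2, -3.01 for Ebf1, -3.78 for Fam129c, -1.09 for Ighm, -1.85 for Irf4, -1.73 for Lef1, -1.21 for Ly6d, -2.21 for Siglech, -2.08 for Spib and -3.63 for Vpreb3. Interferon-induced genes had -0.99 for Gbp2, -2.81 for Ifi205, -3.58 for Ifit3, -3.81 for Ifit3b, -0.59 for Igtp, -2.81 for Iigp1, -1.57 for Irgm1, -1.50 for Isg15, -2.16 for Oasl2, -2.36 for Rsad2 and -2.67 for Serpina3f. Myeloid and antigen presentation genes had 2.52 for Apoe, 1.88 for C1qa, 1.55 for C1qc, 1.75 for C4b, 0.89 for Camp, 0.93 for Ccl4, 1.18 for Cd14, 1.21 for Csf1r, 1.09 for Fn1, 0.53 for H2-Aa, 1.64 for H2-Ab1, -0.88 for Il1r2, -0.82 for Ly6c2, 0.93 for Mpo, -0.70 for Ms4a6c, 0.98 for Prtn3, -0.72 for S100a9 and -0.82 for Tnfrsf11a. Erythroid and megakaryocyte genes had -0.94 for Alas2, 3.43 for Car1 (fitted 7.35 without control SCFA 2, on 1 count), 2.12 for Gp9, 0.80 for Itgb3, 1.40 for Tubb1 and 1.80 for Vwf. Immediate early genes and genes around STAT3 had 1.67 for Egr1, 2.23 for Egr2, 1.18 for Fos, 1.31 for Ier3, 1.73 for Junb, 1.73 for Lrg1, 1.76 for Socs3 and 0.88 for Stat3. Genes of metabolism, mitochondria and ribosomes had 1.44 for Aldoa, -0.88 for Cycs, 1.08 for Eno1, 1.13 for Gapdh, 1.22 for Gpi1, -0.87 for mt-Co1, -2.04 for mt-Co3, -1.09 for mt-Cytb, -0.95 for Ndufb5, 1.25 for Rpl18, 0.93 for Rplp0 and 1.43 for Slc16a3. Cell cycle and heat shock genes had -0.91 for Ccnb1, -0.78 for Cdk1, -1.20 for Hsp90aa1, -2.58 for Hspa1a, -0.86 for Hspa5, -0.87 for Hspd1, -1.16 for Kif11, -0.52 for Mcm6 and -0.91 for Rrm2. Other genes had 2.15 for Asprv1, -5.11 for Cecr2, 3.68 for Colec12 (6.38 without control SCFA 1), -2.82 for Dus4l, -1.98 for Hdac9, -1.06 for Hpgds, 1.91 for Plxna4, -3.62 for Reln, -1.23 for Tmem108 and -1.25 for Zscan26. For genes with 0 counts in homozygous SCFA mice the values were at most -5.76 for Col5a3, -7.78 for Gfra1, -6.75 for Lgr5, -8.76 for Rag1, -8.86 for Rag2, -6.07 for Sertad4, -2.18 for Tmem132e and -6.75 for Tnfrsf19, and the fitted -7.53 of Igll1 rests on 3 counts. For lists the medians were 0.64 for megakaryocyte and platelet genes, -2.41 for B lineage genes, -1.44 for plasmacytoid dendritic cell markers, 0.92 for STAT3 target genes, -1.69 for type I interferon response, 1.04 for immediate early genes, -0.75 for heat shock genes, -0.68 for G2 and M phase genes, 1.08 for glycolysis and -1.01 for mitochondrially encoded genes; only type I interferon and B lineage genes held with an estimated correlation (adjusted p of the other 8 from 0.117 to 0.493). Adjusted p of all these lay between 1.9e-19 and 0.0448.

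B lineage genes fell in homozygous mice and fell further under SCFA. Scaling as the whole cause is argued against: it moves all genes alike, and the list's median lay -2.33 from that of all genes (camera adjusted p = 4.0e-04 with an estimated correlation), whereas RLE factors (-2.43) moved all genes by too little to test it. Equal dilution of all B lineage cells is argued against: under SCFA 8 precursor genes fell by 4.45 more on the mean log2 scale than 9 mature ones (exact two-sided permutation p = 0.000206), with Rag1 and Rag2 at their bounds and Igll1 fitted from 3 counts. A date effect shared by both genotypes drops out of the interaction by design, so the list's median of -0.18 in control mice between the dates tests nothing. Fewer B cell precursors, or lower expression in them, may account for the deeper fall, a hypothesis left untested. An effect of date, cage or culture on this 1 group cannot be told apart from it.

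Type I interferon genes were high in untreated homozygous mice. Their mean log2 fold change of 1.39 (28 genes) lay 0.633 above that of 16 monocyte markers (0.761, two-sided permutation p = 0.00812). The p takes genes as replicates, so a larger share of monocytes stays open. A deviating library is argued against by the lowest median of 1.22 in 12 fits without 1 library. All untreated libraries share 1 date, so the median of 0.16 in control mice between dates tests nothing. An effect of genotype, or an exposure of that group alone such as an infection in a cage, may account for it; both are hypotheses left untested.

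More genes had an interaction than an averaged genotype or treatment effect. A single library does not explain it, since the lowest count without 1 library was 2540 (without control SCFA 3; 2599 without homozygous SCFA 2). Nor does a shift of all genes as the whole cause, since no common shift from -1 to 1 brought the count under 3828; RLE factors (3899 genes) moved too little to test it. An offset shared by the 3 libraries of a group, as from joint culture, may give this pattern and cannot be told apart from a true interaction: Spearman's rho of the 2 genotype effects was -0.105 (-0.0299 without control untreated 2, -0.0583 without homozygous untreated 2, -0.0615 without control SCFA 3 and -0.0629 without homozygous SCFA 2), which both allow.

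Other splits of the same libraries were counted. For genotype without SCFA 1 of 10 splits, the real one, gave as many genes (2323, highest other 1), likewise 1 of 10 under SCFA (2722, highest other 0), 1 of 10 for SCFA in control mice (3432, highest other 1) and 1 of 10 in homozygous mice (1501, highest other 0); 10 splits are too few for a share under 0.05. For the interaction 1 of 100 splits reached 3938 (highest other 1585), and for the averaged genotype effect 2 of 100 reached 1585. The other, with 3938, exchanges the genotypes within 1 date and is the interaction itself. The next, with 1482, exchanges control untreated 2 and 3 with homozygous untreated 2 and 3. Both shares exclude chance only if a group's libraries are independent, which is not known.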

How the results depend on the processing

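None of the alternatives was chosen only after the result was seen. No result reversed under any alternative run. Of 233 named gene results, 231 kept their side of the threshold with RLE factors, 227 without a filter and 226 with DESeq2 and with limma-voom each, 227 with the replicate block, 138 of 144 with that block within label date and 177 of 189 in fits of only the groups compared (11 weaker); over 2796 results without 1 library, 147 were weaker and 10 stronger. Of 222 list results, 221 kept it with RLE factors, 62 were weaker with an estimated correlation, and fry made 6 weaker and 57 stronger.

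Counts of called genes without 1 library ranged from 823 to 4454 for genotype without SCFA, 1453 to 3351 under SCFA, 690 to 5269 for SCFA in control mice, 758 to 2092 in homozygous mice, 2540 to 5538 for the interaction and 1260 to 2122 for genotype averaged; the correlation of the genotype effects ranged from 0.0903 to 0.181. Limma-voom called 3922 for genotype without SCFA, 4762 under SCFA, 2483 averaged and, for SCFA in homozygous mice, 2988 (DESeq2 2310). Fits of only the groups compared called 3475 for genotype under SCFA and 1723 for SCFA in homozygous mice. With control untreated libraries they called 827 for genotype and 1844 for SCFA. That group's pairs reached chi-square 140 (others up to 48.3). The cause was not tested.

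With the replicate number as a replicate block the counts were 2067, 2447, 3249, 1282, 3715 and 1472 in the same order, with a correlation of 0.169; as a replicate block within label date they were 1107 for genotype without SCFA and 1728 under SCFA. Equal numbers do not pair the libraries: deviations of the 6 same-date pairs correlated at -0.114 to 0.0182, and 4 of 12 libraries correlated best with their own number. Depth limits genes at 0 counts to bounds.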

Other observations

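The genes and families here were chosen only after their values were seen; the test near Rosa26 was chosen beforehand. Of the stefin genes, which encode inhibitors of cysteine proteases and were not tested as a group, Stfa1 (chromosome 16) rose in homozygous mice without and under SCFA by 1.92 and 2.03 on the log2 scale (adjusted p = 0.00192 and 7.4e-04) and Stfa2 by 2.83 and 2.89 (adjusted p = 2.8e-04 and 9.6e-05). Stfa3 had adjusted p = 0.00696 and 0.133 (interaction 0.15). Among guanylate-binding protein genes, 8 of 11 rose without SCFA (median 1.68, camera adjusted p = 3.2e-07 over 334 families; adjusted p = 0.0443 with an estimated correlation). Under SCFA Gbp2, Gbp3 and Gbp7 rose by 2.21, 1.31 and 0.74 (adjusted p = 3.1e-06, 7.3e-05 and 0.00171), Gbp9 fell by 0.85 (adjusted p = 4.2e-04) and the other 7 did not pass. The interaction passed for Gbp2, Gbp4, Gbp6, Gbp7, Gbp8 and Gbp9 (adjusted p from 8.8e-05 to 0.0201).

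Of the immunoglobulin variable segments, under SCFA 0 rose and 44 fell of 74 of the heavy chain, and 0 rose and 50 fell of 84 of the kappa chain (adjusted p = 5.6e-04 and 0.00157 with an estimated correlation). Ighm had 1460 ± 128 CPM in control untreated, 520.8 ± 24.2 in homozygous untreated, 1285 ± 11.2 in control SCFA and 215 ± 18.3 in homozygous SCFA libraries (mean ± SD, n = 3), whereas Igha, the heavy chain of IgA, had 11.7 ± 3.22, 17.9 ± 3.87, 2.95 ± 1.35 and 15.8 ± 3.33 CPM. Igha rose by 2.41 between genotypes under SCFA (adjusted p = 1.6e-04) and was at 0.61 without SCFA (adjusted p = 0.170; interaction adjusted p = 0.00983).

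Passenger DNA around the targeted allele could give genotype differences near Rosa26 on chromosome 6 (113067428 to 113077333). Within 10 Mb 11 of 126 genes (8.73%) were called for genotype averaged, against 1510 of 14720 (10.3%) elsewhere on autosomes, a ratio of 0.851 (Fisher's exact p = 0.660), which does not point to it.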
